A study of Mus musculus with 6 samples.

How the data were processed

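Gene expression was measured on 6 microarrays, each with total RNA from RAW264.7 cells, an established mouse macrophage line. Per the labels' protocols, the cells had been transfected by lipofection with an empty expression vector or with a vector carrying a recombinant Ms4a8a cDNA, transfectants had been selected with blasticidin, and the cultures were kept for 48 h in standard serum-containing medium. RNA was isolated on silica columns, and biotin-labelled cRNA was prepared by the manufacturer's standard Affymetrix procedure, per the labels' protocols. The labels name 1 clone per arm, clone 3 for the vector and clone 8 for Ms4a8a, with 3 arrays each. The transgene and the clone were therefore the same variable in every comparison. The series' design text names Ms4a8a for the cDNA and the transfectants but Ms4a4a where it describes the expression of the selected clone. The arrays were grouped by their titles, and the level of Ms4a8a on each array was looked at first.

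The values analysed were those of the authors' deposited series table, on a log2 scale, with 1 value per probe set and array. The 6 columns held the same sorted values (largest difference 0), as quantile normalisation gives, with a median of 5.94 and a range from 2.24 to 14.6. The summary method, its background correction and its software were not given in the sources used here. The table had 17370 probe sets, of which 64 were Affymetrix control sets, 16387 had 1 gene symbol in the platform annotation, 0 had several and 919 had none. The number of arrays, not a read depth, limits the precision, and no detection call was used here, so a low value was not read as absence of a transcript. All per-sample columns of the table were used.

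Probe sets are numbered by gene in this annotation, with 1 probe set per gene. The numbers of 16358 of the named probe sets were found among the RefSeq gene IDs of mouse assembly GRCm38.p6. The annotated symbol was equal to the RefSeq symbol for 14580 of them, was a synonym that was replaced by the RefSeq symbol for 1773, and was neither for 5. The 29 probe sets whose number was not found kept their symbol. The assembly was used for names and for the order of neighbouring genes only, since the build behind the probe sets was not given in the sources used here.

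The Ms4a8a clone was compared with the vector clone by limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0), using lmFit and eBayes on the deposited log2 values of all 16387 named genes, with no filter on low values and no offset. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Genes were also counted at an absolute log2 change of 1 or more, which is a 2-fold change. The deposited table came already normalised, and no further scaling was applied. The model, fixed before the data were examined, had no term for the replicate number, and a model with the replicate number as a block was fixed as its alternative. Nothing in the labels says whether the arrays of a clone came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

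The replicate numbers in the titles are shared by the clones. Same-numbered arrays deviated together from the means of their clones, with correlations across genes of 0.709 for number 1, 0.809 for number 2 and 0.865 for number 3. All 3 correlations were above 0.1, the limit set for treating the numbers as pairs, and the source names of the samples pair the arrays in the same way. The vector array 1 correlated about as well with the Ms4a8a array 2 (0.713) as with its own number. The highest correlation with another number was 0.617 for vector array 2 and -0.732 for vector array 3. Number 3 stood apart in both clones, so arrays 1 and 2 deviate from their means together in any order. Passing the limit therefore says little on whether numbers 1 and 2 are pairs. Results of the model with the replicate block are given beside the others where they change a call or a count, and are called blocked below.

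A set of 22 gene lists was fixed from background knowledge before the data were examined. They covered the Ms4a family, alternative (M2) and classical (M1) macrophage activation, interferon-stimulated genes, antigen presentation, glucocorticoid-responsive genes, p38 and AP-1 immediate-early genes, cell cycle and DNA replication, osteoclast genes, lysosome and phagocytosis, sterol biosynthesis and uptake, sterol efflux, glycolysis and hypoxia, the unfolded protein and amino acid stress response, the NRF2 response, pattern recognition receptors, macrophage identity, and cell adhesion, matrix and migration. They also held markers of lymphocytes, of granulocytes and mast cells, of dendritic cells, and of fibroblasts and epithelium. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists. Camera with the correlation estimated for each list and limma's fry were run as alternatives. The count of lists past 0.05 was 0 with an estimated correlation and 0 by fry, with or without the block. At an unadjusted p under 0.05 the estimated correlation gave 1 list and fry 3 without the block, and 0 and 4 with it.

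Genes were named by a rule fixed before the data were examined. Ms4a8a and its family come first. Then come up to 12 genes with the largest rise and up to 12 with the largest fall among genes past the threshold whose 3 arrays of the higher group all lay above those of the other, with the higher mean at or above the median gene (log2 6.05). Of all 16387 genes, 1292 had groups that lay apart in this way, and arrays in random order would give 10%. Predicted and Riken entries were skipped and counted. Of each list, up to 3 members with the largest rise and up to 3 with the largest fall past the threshold were named, or, where none passed, the 2 members with the smallest p. The rule was applied to the model without the block and, in the same form, to the blocked model. Genes named outside the rule are marked as such.

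Alternatives fixed in advance were the replicate block, quantile normalisation and median centring of the columns, filters on low genes, all probe sets in place of named genes, a variance trend with robust estimation, array weights and leaving out each array in turn. The series table was on a log scale with 1 probe set per gene, so alternatives on the offset and on the choice of probe set did not apply. Simulated data had 200 changed genes among 16387 and were drawn 5 times with the spread left by the blocked model. The model without the block recovered 36.4% of changes of log2 1 and 79.4% of changes of log2 2, with 0.4 false calls per simulation. The blocked model recovered 93.6% and 99.6%, with 8.8 false calls per simulation. Same-numbered arrays of both clones were given the same replicate effect, so the pairing was built in. The simulation therefore cannot show which model suits the real arrays. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.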

Results

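Transcript levels were compared between 2 stable clones of the mouse macrophage line RAW264.7, 1 carrying the empty vector and 1 carrying a recombinant Ms4a8a cDNA, on 3 arrays per clone. Ms4a8a belongs to the membrane-spanning 4A family, whose best known member is the B-cell antigen CD20. The series title places the gene in M2-like tumour-associated macrophages and names p38 MAPK and glucocorticoid signalling as its inducers. The comparison asks how expression in a clone with the transfected gene differs from that in the vector clone. The activity of those signals in the 2 clones was not measured. A gene is said to have risen or fallen where its adjusted p passed 0.05 in the model named.

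Ms4a8a was 24.4-fold higher in the Ms4a8a clone, the largest change among the 16387 genes. Its log2 level was 3.21 ± 0.13 (SD, n = 3) in the vector clone and 7.81 ± 0.38 (SD, n = 3) in the Ms4a8a clone, a difference of 4.61 (SE 0.20, limma adjusted p = 0.0121, blocked adjusted p = 0.000424). The vector arrays read 3.07, 3.32 and 3.22, and the Ms4a8a arrays read 7.40, 7.90 and 8.15. In the vector clone between 9.69% and 15.3% of genes lay below it, and in the Ms4a8a clone between 62.8% and 71.0%. The gene is covered by a single probe set whose place relative to the transfected cDNA was not used here, so its signal does not separate the transgene from the cell's own gene. With the vector arrays that close to the bottom of the scale, the fold can be understated. The call was lost in the model without the block when vector array 1 (adjusted p = 0.234), vector array 2 (0.0998), vector array 3 (0.119) or Ms4a8a array 2 (0.107) was left out, with log2 differences of 4.44 to 4.82 over the 6 arrays left out in turn.

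**Figure D1:**
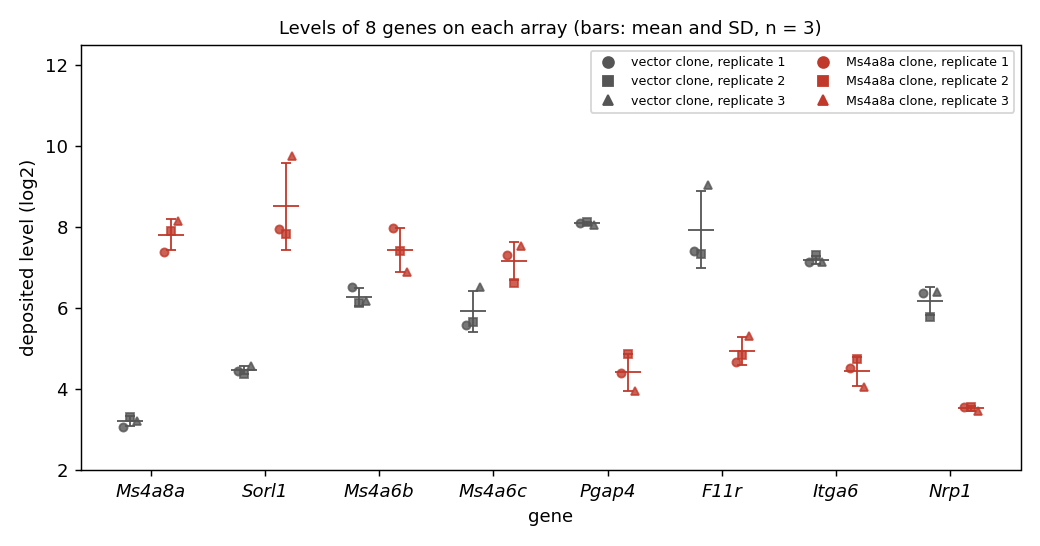
Deposited log2 level of 8 genes (x axis) on each of the 6 arrays (y axis), with the vector clone in grey, the Ms4a8a clone in red, marker shapes for the replicate number, and bars for the mean and SD of 3 arrays. Ms4a8a lies between 3.07 and 3.32 on the vector arrays and between 7.40 and 8.15 on the Ms4a8a arrays. None of the 8 genes overlaps between the clones, which follows from the rule by which genes were named.

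Beyond the transgene, Pgap4, Itga6 and Nrp1 fell in the Ms4a8a clone. Pgap4, a Golgi glycosyltransferase that modifies glycosylphosphatidylinositol anchors, was 12.8-fold lower (log2 8.09 ± 0.03 against 4.42 ± 0.46, SD, n = 3 each; limma adjusted p = 0.0178). The laminin-binding integrin subunit Itga6 was 6.75-fold lower (7.19 ± 0.10 against 4.44 ± 0.35; adjusted p = 0.0212), and Nrp1, a co-receptor for semaphorins and vascular endothelial growth factor, was 6.28-fold lower (6.18 ± 0.35 against 3.53 ± 0.06; adjusted p = 0.0212). In all, 7 of 16387 genes passed without the block, 3 up and 4 down and all by at least 2-fold. The other 3 lay at low levels outside the naming rule and are named after their values were seen, namely Epop (log2 change 2.35), Zfp58 (1.47) and Dpy19l3 (-1.65). At an unadjusted p under 0.05 there were 524 genes, 278 up and 246 down. The count of 7 fell to 0 without vector array 1, vector array 3 or Ms4a8a array 2, to 1 without vector array 2 or Ms4a8a array 1, and was 8 without Ms4a8a array 3. At an unadjusted p under 0.05 the 3 counts of 0 had 330, 783 and 447 genes.

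With the replicate number as a block, 149 genes passed, 75 up and 74 down, and 65 of them changed at least 2-fold, 33 up and 32 down. The 149 held all 7 of the genes called without the block. By the naming rule 63 genes remained, 30 up and 33 down, of which 1 Riken entry was skipped. After Ms4a8a, the largest rise was in Sorl1, a sorting receptor of the low-density lipoprotein receptor family, which was 16.5-fold higher (4.47 ± 0.10 against 8.51 ± 1.08; blocked adjusted p = 0.00953). Next came Tfec, a transcription factor of the Mitf family (6.08-fold), the fatty acid elongation enzyme Hacd1 (5.94-fold), the matrix protein Ltbp2 (5.31-fold), the death-associated protein kinase Dapk1 (4.78-fold) and the poly(A) polymerase Tent5a (4.10-fold). Rises of about 1 log2 unit were seen in Ctf1, which encodes the cytokine cardiotrophin 1 (log2 change 1.32), the chemokine and scavenger receptor Cxcl16 (1.29), the zinc finger gene Zfp799 (1.26), Ms4a6c (1.24) and Ms4a6b (1.16). Their blocked adjusted p-values ran from 0.00596 to 0.0332.

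After Pgap4, the largest blocked fall was in F11r, the junctional adhesion molecule A, which was 7.92-fold lower (7.93 ± 0.95 against 4.94 ± 0.34; blocked adjusted p = 0.00747), followed by Itga6, Nrp1 and the B-cell scaffold gene Bank1 (5.13-fold lower; 0.00237). Smaller falls were seen in the acyl-CoA synthetase Acsbg1 (2.75-fold lower), cyclin D2 (Ccnd2, 2.61-fold), the membrane serine protease St14 (2.50-fold), the endocytic adaptor Dab2 (2.45-fold) and the lipid-modifying enzyme Plaat3 (2.31-fold). The interferon-inducible genes Ifi47 and Mndal were 2.73-fold and 2.40-fold lower. These 7 genes had blocked adjusted p-values from 0.00335 to 0.0486. Of the genes called with the block, Sorl1, Bank1, F11r and the others not named for the model without it did not pass there (Sorl1 adjusted p = 0.245, Bank1 0.0604, F11r 0.496). Without both arrays of number 3 the blocked model called 434 genes, 258 up and 176 down, and 148 of the 149 were among them. Fewer were kept in the other refits. Without both arrays of number 1 it called 101 genes, with 84 of the 149 among them. Without those of number 2 it called 104, with 85 of the 149. With numbers 1 and 2 of the Ms4a8a clone exchanged it called 67, with 65 of the 149.

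**Figure D2:**
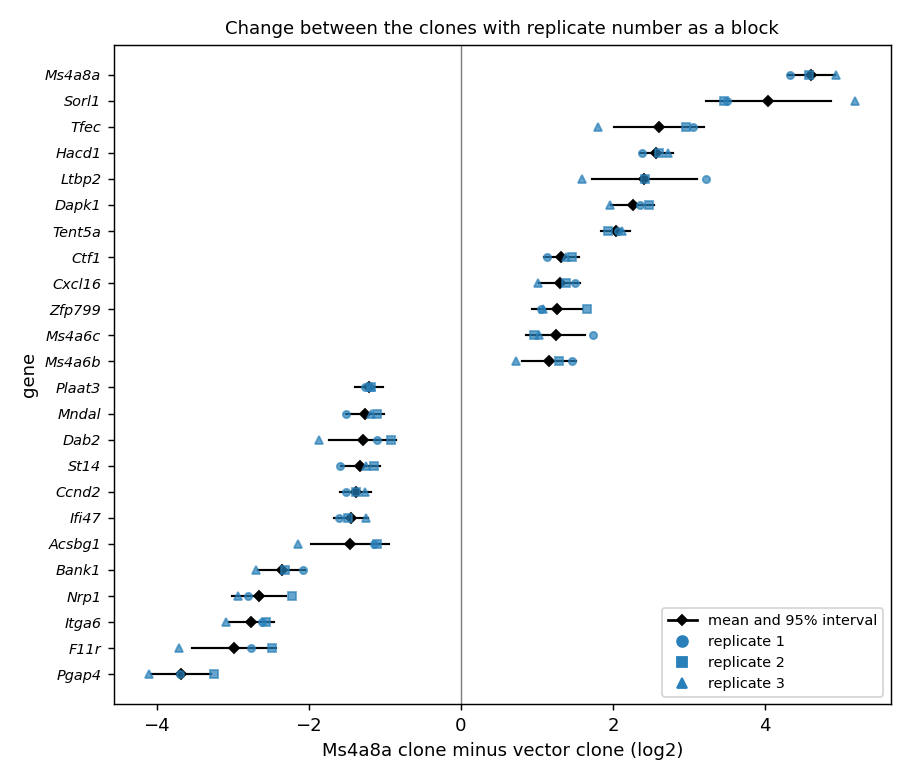
Log2 difference of the Ms4a8a clone from the vector clone (x axis) for the 24 genes named from the blocked model (y axis), with diamonds and lines for the mean and its 95% confidence interval and blue markers for the difference at each replicate number. The means run from Ms4a8a at 4.61 to Pgap4 at -3.68. All 3 markers of every gene lie on the same side of 0, which follows from the naming rule.

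Within the Ms4a family, 3 of 13 measured members rose in the blocked model, Ms4a8a, Ms4a6c and Ms4a6b, and the other 10 did not pass. Adjusted over the list alone there were 4. The remaining relative, Ms4a6d, read 7.24 ± 0.99 in the vector clone and 8.09 ± 0.80 in the Ms4a8a clone (log2 difference 0.85, blocked adjusted p = 0.0625). Ms4a15, the other member above the median gene, differed by -0.08 (blocked 95% interval -0.28 to 0.12). Without the block Ms4a8a alone passed over all genes, and 2 members did adjusted over the list alone. The list's camera adjusted p was 0.0661, and 0.0409 with the block (adjusted p = 0.615 with an estimated correlation). These values include the transfected gene. Over the other 12 members, a test chosen after the data were seen, the camera adjusted p was 0.705 (blocked 0.329), so the list's call rested on Ms4a8a. Of those 12, 5 had a positive change (mean 0.23, median -0.03). With Ms4a8a in the list, the blocked p was 0.0613 without both arrays of number 1, and with numbers 1 and 2 of the Ms4a8a clone exchanged it was 0.0595, while without the block it was 0.0333 without Ms4a8a array 3, 9.76e-06 among genes at or above the 25th percentile, 0.0181 with array weights and 0.0200 for numbers 1 and 2 alone.

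Lipid and redox gene groups lay higher in the Ms4a8a clone as groups, though no member of them passed on its own over all genes. All 16 measured genes of sterol biosynthesis and uptake had a positive change (median log2 0.19; camera adjusted p = 0.000387, blocked 1.58e-06; adjusted p = 0.427 and blocked 0.535 with an estimated correlation). Adjusted over the list alone, 5 rose in the blocked model. Nsdhl and Mvd, which encode enzymes of the pathway, had log2 changes of 0.43 and 0.44. The call held without each array in turn. The sterol efflux list had 15 measured genes, chosen as targets of the liver X receptors and not limited to genes of efflux. Of these 15, 12 had a positive change (median 0.35; camera adjusted p = 0.0203, blocked 0.00186; adjusted p = 0.427 and blocked 0.535 with an estimated correlation), and 5 rose in the blocked model adjusted over the list alone. Pltp, a phospholipid transfer protein, and Smpdl3a differed by 0.67 and 0.96, and Nr1h3, which encodes such a receptor, by 0.52. The call without the block was lost without vector array 3 (0.0738) or Ms4a8a array 3 (0.0522) and among genes at or above the median level (0.0547). Of 22 genes of the NRF2 oxidative stress response, 19 had a positive change (median 0.19; camera adjusted p = 0.0303, blocked 6.68e-05; adjusted p = 0.614 and blocked 0.535 with an estimated correlation), among them Blvrb (0.54) and Gclm (0.39), and 2 rose in the blocked model adjusted over the list alone. That call without the block was lost without vector array 3 (0.304), Ms4a8a array 1 (0.355) or Ms4a8a array 2 (0.143). The median change of the NRF2 list was 0.28, 0.15 and 0.08 at numbers 1, 2 and 3, with 2, 4 and 8 negative members. Of its 22 genes, 14 were lowest on number 3 in both clones.

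The macrophage, pattern recognition and osteoclast lists tested upward in the blocked model, with members in both directions. In the macrophage identity list, Sirpa, the inhibitory receptor for the surface protein Cd47, rose (log2 change 1.28, blocked adjusted p = 0.0213) and the other 27 of 28 members did not pass, with 17 positive and 11 negative changes in all. Adjusted over the list alone, 10 rose and 1 fell in the blocked model, and the list's camera adjusted p was 0.0384 (blocked 0.00186; adjusted p = 0.807 and blocked 0.535 with an estimated correlation). Among 26 pattern recognition genes, Clec7a, the beta-glucan receptor dectin-1, rose by 2.07 (blocked adjusted p = 0.0366), and 3 rose in that model adjusted over the list alone, with 19 positive and 7 negative changes in all. That list's camera adjusted p was 0.0180 (blocked 0.00375; adjusted p = 0.588 and blocked 0.535 with an estimated correlation). In the osteoclast list 13 of 19 members had a positive and 6 a negative change, none passed over all genes, and 7 rose and 1 fell adjusted over the list alone in the blocked model. Acp5, the tartrate-resistant acid phosphatase, read 6.91 ± 1.42 and 9.55 ± 0.53 (blocked adjusted p = 0.0647), and the proton pump subunit gene Atp6v0d2 read 4.08 ± 0.07 and 6.18 ± 1.19 (0.0973). The list's camera adjusted p was 0.0505, and 0.00994 with the block (adjusted p = 0.535 with an estimated correlation). Of 30 lysosome and phagocytosis genes, 24 had a positive change and none passed over all genes, with 3 up and 3 down adjusted over the list alone in the blocked model. Ctsc differed by -0.45 and Gpnmb read 8.27 ± 3.33 and 7.27 ± 2.86, and the camera adjusted p was 0.475, or 0.0482 with the block (adjusted p = 0.622 with an estimated correlation). The macrophage identity call without the block was lost without vector array 1 (0.351) or vector array 2 (0.504) and turned direction without Ms4a8a array 3 (0.866). The pattern recognition call was lost without vector array 1 (0.306), vector array 2 (0.105) or Ms4a8a array 3 (0.399), and the blocked lysosome call without both arrays of number 1 (0.483) or number 2 (0.282), with numbers 1 and 2 of the Ms4a8a clone exchanged (0.0680), among genes at or above the 25th percentile (0.0817), or with Ms4a8a out of its family list (0.0531), which moves the adjustment over lists. Without the block the osteoclast list passed without Ms4a8a array 1 (0.0434) or 3 (0.0224), among genes at or above the median level (0.0294) or the 25th percentile (0.0227), with array weights (0.0103) and for numbers 1 and 2 alone (0.00151). The lysosome list did so without vector array 3 (0.000362), with array weights (0.0261) and for numbers 1 and 2 alone (0.00764).

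Proliferation and stress response genes lay lower in the Ms4a8a clone, mostly at number 3. Of 45 measured cell cycle and DNA replication genes, 39 had a negative change (median -0.32), Ccnd2 fell in the blocked model, and the other 44 did not pass. Ccnd1 differed by -0.42 (blocked adjusted p = 0.161). The list's camera adjusted p was 0.0180 (blocked 3.04e-07; adjusted p = 0.807 and blocked 0.535 with an estimated correlation), with 1 up and 1 down adjusted over the list alone in the blocked model. Its median levels were 10.6, 10.5 and 9.47 on vector arrays 1, 2 and 3 and 10.6, 10.6 and 8.47 on the Ms4a8a arrays, and its median change was -0.14, -0.08 and -0.66 at the 3 numbers. Without both arrays of number 3 the blocked p was 0.00345, still down. Of 31 genes of the unfolded protein and amino acid stress response, 25 had a negative change (median -0.18; camera adjusted p = 0.0303, blocked 0.000384; adjusted p = 0.467 and blocked 0.592 with an estimated correlation). The median change of the stress list was -0.03, -0.07 and -0.33 at the 3 numbers. Ddit4, an inhibitor of mTOR signalling, fell by 0.53 in the blocked model (adjusted p = 0.0436), the sole member past the threshold there and also adjusted over the list alone. Its difference was -0.58, -0.48 and -0.54 at the 3 numbers. Without the block and vector array 3 it was 0.23, in a fit that kept the high Ms4a8a array 3 (10.2). Antigen presentation genes had a camera adjusted p of 0.0915, and 0.0262 down with the block (adjusted p = 0.535 with an estimated correlation). None of their 25 members passed, also adjusted over the list alone, and Tap2 and H2-Ob differed by -0.31 and -0.65. The cell cycle call without the block was lost with array weights (0.194) and without vector array 1 (0.307) or vector array 2 (0.250), and it turned direction without Ms4a8a array 3 (0.0268). The stress response call was lost with array weights (0.457) and without vector array 3 (0.532), Ms4a8a array 3 (0.406) or both (0.376), and with the block, without both arrays of number 3, both it (0.247) and the antigen presentation call (0.0949) were lost. The blocked antigen presentation call was also lost among genes at or above the median level (0.305) or the 25th percentile (0.0560), and without the block the list passed downward without vector array 1 (0.0496), vector array 2 (0.0422) or Ms4a8a array 3 (0.0153).

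**Figure D3:**
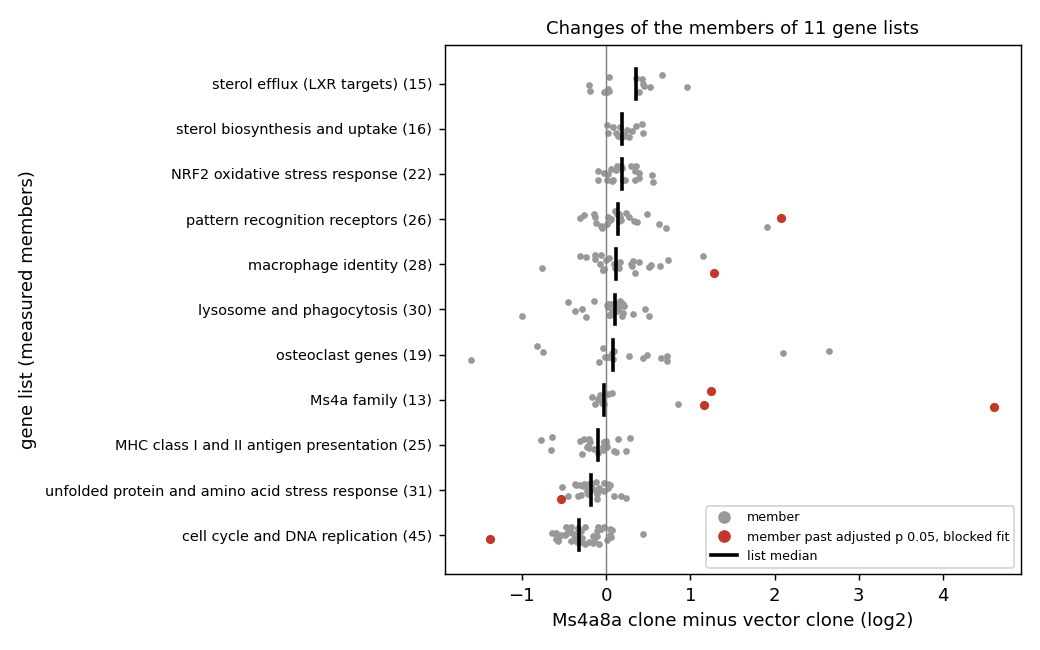
Log2 difference of the Ms4a8a clone from the vector clone (x axis) for each measured member of the 11 gene lists past camera's threshold in the blocked model (y axis, number of members in brackets), with red points for members past adjusted p 0.05 in that model and black bars for list medians. Medians run from -0.32 for the cell cycle to 0.35 for sterol efflux.

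The alternative activation, glucocorticoid and p38 lists, which lie nearest to the series title, did not pass as groups with all arrays. Classical activation did not either. The title names p38 MAPK and glucocorticoid signalling as inducers of Ms4a8a, which a clone with the transfected gene does not test. Among 37 alternative activation genes, Clec7a rose and the lectin Clec10a fell by 0.88 in the blocked model (adjusted p = 0.0170), and 35 did not pass. The list's camera adjusted p was 0.711 (blocked 0.724), with a median of -0.01 against a mean of 0.08 and a test pointing up. Among 37 classical activation genes the co-stimulatory molecule Cd80 fell by 1.05 in the blocked model (adjusted p = 0.00747) and 36 did not pass (camera adjusted p = 0.969, blocked 0.992). Of 31 glucocorticoid-responsive genes, Tsc22d3, which encodes the leucine zipper protein GILZ, rose by 0.76 (0.0469), Ddit4 fell and 29 did not pass (camera adjusted p = 0.842, blocked 0.724; median -0.03, mean 0.04 and test pointing up). Of 36 p38, AP-1 and immediate-early genes, the phosphatase gene Dusp6 fell by 2.12 (blocked adjusted p = 0.0241), Jun fell by 0.65 (0.0394) and 34 did not pass (camera adjusted p = 0.969, blocked 0.724, median 0.04). Adjusted over the list alone, the blocked model had 3 up and 1 down for alternative activation, 1 and 1 for classical activation, 2 and 3 for the glucocorticoid list, and 3 and 4 for the p38 list. Without the block none of these members passed, over all genes or adjusted over the list alone. The classical activation list turned up without vector array 3 (camera adjusted p = 0.0302), where the p38 list also passed (0.00957). That fit kept Ms4a8a array 3, and both lists lay higher on number 3 in both clones. Classical activation had medians of 6.39 and 6.29 there against 4.94 to 5.38 on the other arrays, and the p38 list 8.10 and 8.21 against 6.92 to 7.35. Without both arrays of number 3, neither list passed in the blocked model (camera adjusted p = 0.0949 and 0.0876).

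Among 38 interferon-stimulated genes, Ifi47 fell by 1.45 and the RNA sensor gene Ifih1 by 1.23 in the blocked model, 3 fell adjusted over the list alone, and the camera adjusted p was 0.702 (blocked 0.418). None of 24 glycolysis and hypoxia genes passed over all genes, 1 rose adjusted over the list alone in the blocked model, and Aldoc and Adm differed by 0.55 and -1.41. That list's camera adjusted p was 0.954 (blocked 0.887) with a median of -0.03, a mean of -0.01 and a test pointing up. It passed upward without Ms4a8a array 1 (0.0357) and downward without Ms4a8a array 3 (0.000202) or, with the block, without both arrays of number 3 (0.0261). None of 34 adhesion, matrix and migration genes passed over all genes, with 2 up and 3 down adjusted over the list alone in the blocked model. The urokinase gene Plau read 8.75 ± 0.57 in the vector clone and 6.16 ± 0.71 in the Ms4a8a clone (blocked adjusted p = 0.0699) and the integrin subunit Itgb7 differed by -0.73 (0.0530). The list's camera adjusted p was 0.805 (blocked 0.724), with a median of 0.00, a mean of -0.02, and tests pointing down without the block and up with it.

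Markers of other cell types gave no list past the threshold with all 6 arrays and all genes in either model. Of 17 lymphocyte markers the immunoglobulin gene Ighm fell by 0.61 in the blocked model (adjusted p = 0.0448) from a level of 11.2 ± 0.46 in the vector clone, 1 fell adjusted over the list alone, and the camera adjusted p was 0.254 (blocked 0.185). Dendritic cell markers had a camera adjusted p of 0.0550 (blocked 0.157) with 12 measured and 1 up adjusted over the list alone in the blocked model, and Cd83 and Cd24a differed by 1.07 and -0.35. That list passed downward without the block with trended and robust variances (0.0428) and without vector array 2 (0.0488), Ms4a8a array 1 (0.0434) or Ms4a8a array 3 (0.0224). The 19 granulocyte and mast cell markers (0.711, blocked 0.851) and the 18 fibroblast and epithelial markers (0.524, blocked 0.524) had no member past the threshold, also adjusted over the list alone. S100a9 and Mcpt8 differed by 0.20 and -0.14, and Pdgfrb and Cldn4 by 0.48 and 0.17. Cd24a, S100a9 and Mcpt8 lay near the bottom of the scale in both clones, with clone means from 2.78 to 3.55.

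Without the block no list other than the Ms4a family had a member past the threshold over all genes, and the naming rule then takes the 2 members with the smallest p. Those not given above were Cd163 (log2 change 0.31) and Trem2 (0.48) for alternative activation, Csf2 (0.51) for classical activation, Ifit2 (-1.06) for interferon, H2-Eb1 (-0.20) and Ciita (-0.10) for antigen presentation, Cd163 again for the glucocorticoid list, and Myc (0.85) and Mapk11 (-0.23) for the p38 list. They were also Mitf (0.66) for osteoclasts, Lipa (0.51) for lysosomes, Msmo1 (0.36) for sterol biosynthesis, Abca1 (0.45) for sterol efflux, Higd1a (0.23) and P4ha2 (-0.81) for glycolysis and hypoxia, Phgdh (-0.28) and Slc7a5 (-0.35) for the stress response, and Taldo1 (0.39) for NRF2. The remaining ones were Irak1 (0.23) and Clec4n (1.91) for pattern recognition, Ccr2 (0.39) for macrophage identity, Cd9 (0.40) for adhesion, Cd5 (-0.49) for lymphocytes and Xcr1 (-0.22) for dendritic cells. Cd163, Xcr1, Cd5 and P4ha2 lay near the bottom of the scale, with clone means from 2.60 to 3.80.

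The arrays of number 3 stood apart in both clones, which sets the spread that the model without the block works against. The first principal component, with 76.6% of the variance, placed the vector and Ms4a8a arrays of number 3 at 45.9 and 55.9 and the other 4 between -29.3 and -19.4. The second, with 12.8%, separated the clones. Across genes, arrays correlated at 0.965 to 0.998. Between replicate numbers 4938 of 16387 genes differed (limma F test in the blocked model), of which 2368 were highest and 2534 lowest on number 3, and 107 of the 149 genes called between the clones were among them. Of the lists above, macrophage identity had median levels of 10.1 and 10.2 on the number 3 arrays of the vector and Ms4a8a clones and 7.30 to 8.01 on the others. Cell cycle genes had 9.47 and 8.47 against 10.5 to 10.6. Medians over numbers also ranged by 1.34 for classical activation, 1.23 for glycolysis and hypoxia, 1.02 for the p38 list, 0.98 for the glucocorticoid list, 0.83 for adhesion, 0.81 for antigen presentation, 0.75 for the stress response, 0.71 for lysosome genes, 0.64 for pattern recognition and 0.47 for interferon-stimulated genes. The 3' to 5' difference of the 4 control transcripts was also highest on number 3 in both clones. It read 0.83, 0.86 and 1.39, then 0.89, 0.90 and 1.46 for the transferrin receptor, 0.47, 0.50 and 0.91, then 0.33, 0.37 and 0.86 for pyruvate carboxylase, 0.17, 0.17 and 0.62, then 0.13, 0.17 and 0.45 for beta-actin, and -0.18, -0.17 and -0.12, then -0.19, -0.16 and -0.06 for Gapdh. Fitted to the arrays of numbers 1 and 2 alone, an alternative chosen after the data were seen, the model without the block called 147 genes, 79 up and 68 down, with all 7 among them.

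**Figure D4:**
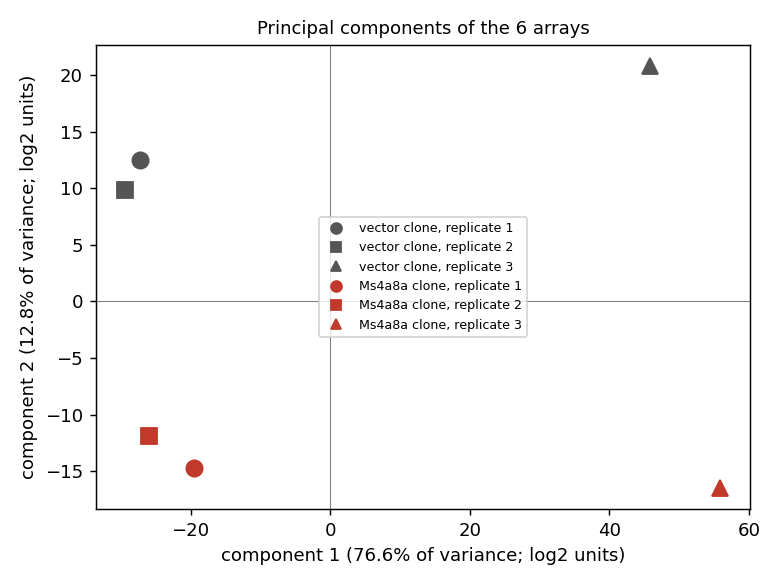
Position of the 6 arrays on principal components 1 (x axis) and 2 (y axis) of the log2 values, with the vector clone in grey, the Ms4a8a clone in red and marker shapes for the replicate number. The number 3 arrays lie at 45.9 and 55.9 on component 1, and the clones lie on opposite sides of 0 on component 2.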

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

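The blocked fit to all probe sets was added after the data had been seen, while the tests of other groupings were fixed before their results were. Among the 919 probe sets without a gene symbol, which no comparison above used, 2 differed between the clones in the blocked model fitted to all probe sets. The first changed by -0.65 on the log2 scale (limma blocked adjusted p = 0.0420, lower in the Ms4a8a clone at all 3 numbers), and the other by 1.39 (0.0457, higher at all 3 numbers). Neither passed without the block, and their genes were not named here.

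The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of these, the real one, gave a count of 7 genes or more without the block, while the highest of the others gave 0. With the block, 4 splits part every pair of same-numbered arrays, and 1 of these, the real one, reached 149 genes, while the highest of the others gave 0. The splits are too few for a share under 0.05.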

How the results depend on the processing

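The fit to arrays of numbers 1 and 2 alone, the family list without Ms4a8a and all alternatives within the blocked model were chosen after the data were seen. Without the block, 7 genes passed, all at 2-fold. The replicate block gave 149 (65 at 2-fold), array weights 47 (33), trended and robust variances 12 (12), the arrays of numbers 1 and 2 alone 147 (82), and genes at or above the median level 1 (1), a filter that removed Ms4a8a and left Pgap4. Leaving out each array gave 0 to 8 genes at either threshold. Quantile normalisation and median centring moved nothing, since the columns already shared 1 distribution, the 25th percentile filter and all probe sets kept 7, and offset and probe set alternatives were not run. The Ms4a8a change ran from 4.44 to 4.82 over the arrays left out, past the threshold without Ms4a8a array 1 or 3 and not without the others.

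In the blocked model, exchanging numbers 1 and 2 of the Ms4a8a clone gave 67 genes against 149, leaving out a pair gave 101 to 434 (64 to 120 at 2-fold, against 65), and the median filter gave 43 at 2-fold. The cause of the rise to 434 was not tested. Of the 22 lists, 7 passed without the block and 11 with it, 7 and 9 with Ms4a8a out of its family list, and 0 and 0 with an estimated correlation or by fry, where 1 and 3 (blocked 0 and 4) had an unadjusted p under 0.05. Leaving out arrays turned, with a call before or after the turn, the direction of classical activation (adjusted p 0.0302 to 0.705), cell cycle (1.02e-05 to 0.307, reversed at 0.0268), glycolysis (0.000202 to 0.659; blocked 0.0261 to 0.568) and macrophage identity (3.61e-05 to 0.866). Each of these turns came with number 3 left out in 1 clone or both. Without the block, such a fit kept the number 3 array of the other clone and so set the clones against each other unequally. Macrophage identity had medians of 10.1 and 10.2 on number 3 against 7.30 to 8.01 elsewhere, and cell cycle 9.47 and 8.47 against 10.5 to 10.6. With the block, the glycolysis list had median changes of -0.17, -0.08 and 0.26 at the 3 numbers, so its direction hung on number 3. What set number 3 apart stays open. Ddit4 turned too (log2 -1.29 to 0.23), without a call in the model without the block. Its value of 0.23 set an average that kept Ms4a8a array 3 (10.2) against vector arrays 1 and 2 (8.63 and 8.30), while its difference was -0.58, -0.48 and -0.54 at the 3 numbers. Without the block, the antigen presentation, alternative activation, adhesion, glucocorticoid, interferon, lysosome and p38 lists, none of which that model called before any change, also turned in at least 1 alternative, with an adjusted p above 0.05 at the turn. Array weights gave 8 lists, 8 up and 0 down, against 5 and 2. Over the alternatives of the lists called before any change, 85 tests kept and 32 lost the call without the block, and 75 kept and 34 lost it with the block, while 26 and 0 tests of the other lists gained a call in the same direction. Of the values for named genes over the alternatives to the model without the block, 65 kept, 34 lost and 75 gained a call, and 1046 stayed without one, 7 of these with a turned direction, Ddit4 among them. The counts without the block include quantile normalisation and median centring, which could change nothing. The list counts of both models also include the family list without Ms4a8a, which could move the other lists only through the adjustment. The kept counts therefore overstate stability. The block changed no other call than those given beside the results. Signal near the bottom of the scale limits low genes such as Ms4a8a in the vector clone.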

Other observations

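Of the tests below, those of RNA degradation, of each kind of other cell, of slower growth, of transgene signal at Ms4a6 probe sets and of a change across the Ms4a cluster were chosen after the result was seen, and the genes in this and the next paragraph were named after their values were seen. Genes that were higher on number 3 in both clones included Gas6, Fcgr3 and Cxcl2, and all those named in this paragraph passed the F test of the replicate number. The bridging ligand Gas6 read 4.31 and 4.25 on vector arrays 1 and 2 and 9.57 on array 3, and 3.92, 4.07 and 10.1 on the Ms4a8a arrays (limma adjusted p = 0.000220 for the replicate number). The Fc receptor gene Fcgr3 read 5.93, 6.14 and 11.6, then 7.42, 6.47 and 11.97, and the chemokine gene Cxcl2 read 3.57, 3.37 and 8.76, then 3.88, 3.40 and 8.21. Gpnmb, Mpeg1, Ltc4s and the hypoxia-responsive Ndrg1 were also highest there. Genes that were lower on number 3 included the complement regulator Cfp (10.0, 10.7 and 6.06, then 9.01, 9.87 and 5.26), Id3 (7.81, 9.04 and 5.22, then 8.24, 9.80 and 4.94), cyclin E2 (Ccne2; 9.83, 9.90 and 6.75, then 9.68, 9.89 and 5.79), the transferrin receptor (Tfrc; 10.2, 10.4 and 7.03, then 10.1, 10.4 and 6.62) and the cold-inducible Rbm3 (7.21, 7.32 and 3.64, then 7.40, 7.56 and 4.03).

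Among the genes called between the clones in the blocked model, the inflammatory caspase genes Casp1 and Casp4, which are neighbours, rose by 0.79 and 1.10 in the Ms4a8a clone, and the adhesion gene Cd48 fell by 1.08. Tmem38b rose by 1.25 and Hsd3b7, an enzyme of bile acid synthesis, by 0.88.

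The arrays of number 3 stood apart in both clones. A mixture with lymphocytes, fibroblasts or epithelial cells as the whole cause is argued against by the macrophage identity list, which such cells would dilute, since 17 of its 28 members (60.7%) differed between numbers with their highest level on number 3 and 0 with their lowest there, though a smaller share of such cells stays open. A mixture with another cell type that shares macrophage transcripts stays open as well, since the medians of the 4 marker lists moved by at most 0.322 but 62 of the 66 markers lay below the median gene, so that these medians decide nothing, and 1 of 19 markers of granulocytes or mast cells (Prtn3, by 0.889) and 3 of 12 of dendritic cells (Cd83 by 3.99, Irf8 by 1.85 and Tcf4 by 1.24) differed and were highest on number 3. RNA degradation stays open too, since the 3' to 5' difference was highest on number 3 of both clones for 4 of 4 control transcripts. It was higher by 0.560 for the transferrin receptor, 0.483 for pyruvate carboxylase, 0.384 for beta-actin and 0.0938 for Gapdh. None reached 0.774, the median range of the genes that differed between numbers, which was the size set for this test. The size that degradation would need was not measured. The 3' signal of the transferrin receptor was itself lower on number 3 (7.40 and 6.92) than on the other arrays (10.4 to 10.8), so its difference was read at a lower level there. Slower growth of those cultures is a candidate explanation as well, with 86.7% of 45 cell cycle genes lowest on the number 3 array of both clones, while culture density, date and batch are not given in the sources used here and were not tested.

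Called genes also lay near each other, which might reflect a regional or copy number difference between the clones. Of the 149 genes, 7 pairs with the same direction lay within 5 genes of each other, F11r with Cd48 and Ms4a6b with Ms4a6c among them, against a median of 3 in 10000 shuffles of the calls, of which a share of 0.0678 gave 7 or more. That number lies above the median of the shuffles and within their range, so a regional difference and scattered changes cannot be told apart for these pairs. A difference between clones that was there before transfection stays open, as untested, for every gene in the comparison, since each arm is 1 clone.

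Ms4a6b and Ms4a6c rose with Ms4a8a, and Ms4a6d had a positive difference that did not pass. Signal from the transgene at their probe sets could give such a pattern, but as the whole cause it would take a like share of the Ms4a8a rise at each number. The shares on the linear scale were 100.2%, 44.2% and 17.3% for Ms4a6b, and the largest was at least 3.21 times the smallest for each of the 3 genes. A change across the whole Ms4a cluster was looked for in Ms4a15, the other member above the median gene, whose blocked 95% interval ended at 0.12. Ms4a15 showed no such rise, but it is 1 gene and no detection call was used. Apart from Ms4a8a and the Ms4a6 genes, the remaining members had clone means of 2.56 to 3.98, too low to decide. A change across the cluster therefore stays open, as does a change limited to the Ms4a6 genes. A response of the cells to Ms4a8a and a difference between the 2 clones were not separated by the design.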
